A study of Homo sapiens with 4 samples.

How the data were processed

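Ribosome profiling libraries were prepared from 5-FU-resistant HCT-8 cells transfected with a negative control plasmid (NC) or a METTL14 overexpression plasmid (OE), 2 libraries per group. Cycloheximide was used at 100 ug/mL, per the labels. Lysates were digested with RNase and the protected fragments were made into cDNA libraries with a kit that adds adapters to double-stranded cDNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

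The authors deposited 1 file per library with an estimated count per Ensembl gene, in a column of counts per the file headers. Between 13.8% and 14.7% of the values in a library held a fraction, so they were treated like RSEM's expected counts and rounded to whole numbers before any count test. The submitters' processing notes name fastp, Bowtie2, HISAT2, StringTie, RSEM and the build hg18. Their versions, order and settings, the gene annotation, the strand setting and the removal of ribosomal RNA reads are not given in the sources used here. Without strand or multi-read settings, overlapping, antisense and near-identical genes cannot be told apart with certainty. Chromosome positions are not given, since no annotation of that build was used here. Gene symbols are those of the files, of which 19828 (97.6% of the 20323 rows) were found in a RefSeq gene table of another build that was used for this count only. There were 169 rows without a symbol, and 475 symbols were shared by 963 rows, which were kept as separate rows.

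Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10, minimum total 15, proportion 0.7), which left 12560. Libraries were scaled by TMM, with factors of 0.889 and 0.912 for NC and 1.36 and 0.907 for OE. OE was compared with NC by edgeR's quasi-likelihood test with the group as the only term, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The common dispersion was 0.179, a biological coefficient of variation of 0.423, with 2 residual and 3.09 prior degrees of freedom. CPM values, counts scaled to library size, were computed from the deposited counts with the TMM-scaled totals.

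Gene lists were tested with limma's camera on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the lists, beside an estimated correlation and fry, which asks whether a list's genes move on balance in either direction and does not compare them with other genes. Of 44 lists, 42 had at least 5 tested members; markers of endothelial and erythroid cells and of hepatocytes and kidney did not. Of the 42 lists, 13 were called by camera, 0 with an estimated correlation (smallest adjusted p = 0.818; 0 lists at an unadjusted p below 0.05) and 0 by fry (smallest adjusted p = 0.275; 5 lists at an unadjusted p below 0.05). List means and medians are differences of mean log2 CPM. A list's median in an OE library was ranked among the medians of 10000 random lists of the same size, to allow for expression level. The random lists were matched on mean log2 CPM over all libraries, in bins of genes. As that mean includes the OE libraries and the top bins are broad, a dependence on NC level was not fully removed.

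The comparison, the lists, the rule for naming genes and most other settings tried were fixed before the data were examined. The rule named METTL14, then the 12 highest and 12 lowest fold changes among genes past the threshold with a mean of at least 10 CPM and groups that did not overlap. Places that no gene filled went to the smallest unadjusted p under the same conditions, which applied to all of them. Of each list described, up to 4 members with the smallest p were named, as was every tested member of the m6A writer complex; some genes that this rule names are not reported here.

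Replicates were compared first: counts of the NC pair differed by a chi-square of 13.2 per degree of freedom and those of the OE pair by 344.5, so no pair was a repeated library. The steps were tested on simulated data. With counts drawn at the spread of the 4 libraries over 12352 genes, edgeR recovered 23% of 4-fold and 96% of 16-fold changes. Both groups were given the same spread there, while the OE libraries of the data varied more than the NC libraries. For the ER chaperone list shifted by -1 on the log2 scale, camera called it in 20 of 20 draws with the preset correlation. With an estimated correlation it was called in 0 of 20, so that setting missed a shift of this size in these draws. In 20 draws with no shift it was called 0 times. Lists that were not shifted were called 3 times over the 20 draws with the shift and 0 times over those without. Genes were drawn independently of one another in these simulations. The draws therefore do not show how often the preset correlation calls lists whose genes move together. Alternatives were the DESeq2 Wald test, edgeR's likelihood ratio test, RLE and total-count scaling, no filter and a filter of 50 counts, the replicate number as a block, each library left out in turn, and removal of mitochondrial, ribosomal protein and very abundant genes. Summing counts per symbol, thinning libraries to the smallest total and weighting libraries by quality were added after the data were seen. No library of total RNA was used here, so footprint changes are not separated from changes in message amount.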

Results

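Ribosome footprints were sequenced from HCT-8 cells, a human colorectal adenocarcinoma line, in a form resistant to the pyrimidine analogue 5-fluorouracil (5-FU). Cells received either a negative control plasmid (NC) or a plasmid overexpressing METTL14 (OE), and were treated with 100 ug/mL cycloheximide, which holds ribosomes on the messages they translate, before RNase digestion. Each group held 2 libraries, described by the submitters as independent experiments. A footprint count per gene reflects both the amount of a message and its occupancy by ribosomes. No library of total RNA was analysed here, so the values are not translational efficiencies. The comparison of OE with NC addresses which messages gained or lost ribosome footprints when METTL14 was overexpressed in the resistant cells.

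The deposited estimated counts summed to 21846389 in NC replicate 1, 18707758 in NC replicate 2, 7742274 in OE replicate 1 and 24392875 in OE replicate 2, over 20323 genes. Between 13979 and 14360 genes had a count above 0 in a library. A value of 3 counts, the upper limit that a count of 0 allows, corresponded to a footprint count scaled to library size (CPM) of 0.286 in OE replicate 1 and of 0.136 in OE replicate 2. The NC libraries had a Pearson correlation of 0.983 across the log2 CPM of 12560 genes, and the OE libraries 0.863; genes are not independent replicates. The standard deviation of the log2 difference between replicates was 0.46 for NC and 1.30 for OE. The 100 most abundant genes held 19.1% of the counts in OE replicate 1 and between 26% and 27.1% in the other libraries. In OE replicate 1 the median log2 difference from the NC mean ran from 1.17 in the tenth of genes with the lowest NC level to -1.08 in the tenth with the highest, while in OE replicate 2 it stayed between -0.09 and 0.07.

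**Figure D1:**
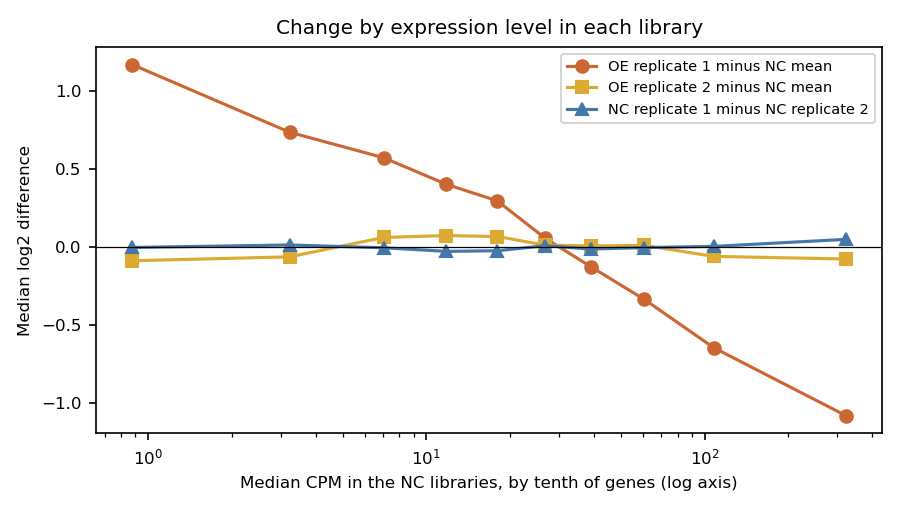
Median log2 difference in footprint CPM (vertical axis) for 10 equal groups of genes ordered by their NC level (horizontal axis, median CPM, log scale). Each point is 1 group of 1256 genes: OE replicate 1 against the NC mean runs from 1.17 to -1.08, OE replicate 2 against the NC mean stays between -0.09 and 0.07, and NC replicate 1 against NC replicate 2 stays between -0.03 and 0.05.

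METTL14 (ENSG00000145388), the RNA-binding partner of METTL3 in the methyltransferase that places N6-methyladenosine (m6A) on messages, had more footprints in both OE libraries than in both NC libraries. Its level was 44.6 and 47.6 CPM in NC and 448 and 91.2 CPM in OE, or 46.1 ± 2.16 against 270 ± 252 CPM (SD, n = 2 each). Exact Poisson 95% intervals, which cover counting error only, were 41.6 to 47.6 and 44.4 to 51.0 CPM in NC, 435 to 461 CPM in OE replicate 1 and 87.3 to 95.3 CPM in OE replicate 2. The log2 fold change was 2.55 (SE 0.81), with an adjusted p of 0.734 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so the difference did not pass the threshold. The DESeq2 Wald test gave 2.51 with a Benjamini-Hochberg adjusted p of 0.0486, the only fit over all 4 libraries that called the gene. In the other fits over all 4 libraries, by edgeR or limma, the adjusted p lay between 0.266 (edgeR's likelihood ratio test) and 0.873 (limma with quality weights), with 0.620 and a log2 fold change of 2.14 with the replicate block. The value depended on which OE library was kept: it was 0.99 without OE replicate 1 (adjusted p = 1.60e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 3.28 without OE replicate 2 (adjusted p = 1.31e-18), both fits resting on the spread of the NC libraries.

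None of the other tested subunits of the m6A writer complex lay higher in both OE libraries. METTL3, the catalytic subunit, had a log2 fold change of -0.10 (SE 0.34), which was 0.18 with library totals as the only scaling. WTAP, which brings the complex to nuclear speckles, had 0.17 (SE 0.32). The scaffold proteins VIRMA and ZC3H13 had -0.17 and -0.63, with ZC3H13 at 142 and 163 CPM in NC and at 163 and 33.1 CPM in OE. RBM15, RBM15B, METTL5 and METTL16 had -0.04, 0.43, 0.06 and 0.25. With library totals as the only scaling VIRMA, CBLL1 and RBM15 turned to 0.29, 0.05 and 0.32. Of the 11 members tested, 1 lay higher in both OE libraries (METTL14), 2 lay lower (TRMT112 with -0.78 and CBLL1 with -0.32) and the rest overlapped between the groups. The list had a mean log2 change of 0.01, a median of -0.05 and a camera test pointing down (Benjamini-Hochberg adjusted p = 0.831). m6A erasers and readers had a mean of -0.18 (camera adjusted p = 0.491), which turned to 0.12 with library totals as the only scaling. Among them the demethylase ALKBH5 had a log2 fold change of 0.67, at 47.8 and 46.8 CPM in NC and 91.8 and 59.3 CPM in OE, and the reader YTHDC2 had -0.55.

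Chaperones of the endoplasmic reticulum (ER) and genes of the unfolded protein response were the group with the lowest camera p among the 42 gene lists tested, and fell. Their mean log2 change was -0.88, a ratio of 0.543 (camera adjusted p = 6.79e-10; adjusted p = 0.818 with an estimated correlation). Footprints were lower in both OE libraries than in both NC libraries for 22 of 27 members and higher for 1. The median change was -1.17 in OE replicate 1 and -0.79 in OE replicate 2, against 0.01 between the NC libraries. Random lists matched on expression had a median of -0.78 in OE replicate 1 and of 0.01 in OE replicate 2, and the chaperones lay at percentiles 0.88 and 0 of them. HSPA5 (BiP), the main Hsp70 chaperone of the ER, had 10530 and 11120 CPM in NC and 2175 and 2638 CPM in OE, a log2 fold change of -2.17 (SE 0.78). The lectin chaperone CALR went from 15680 and 15140 to 3998 and 6755 CPM, and HYOU1, a nucleotide exchange factor for HSPA5, had a log2 fold change of -1.45 (SE 0.57). HSPA5, CALR and HYOU1 were picked after their values were seen; the members with the smallest p were CREB3L2, SEC24D, MANF and SEL1L, with log2 fold changes of -0.93, -1.07, -1.35 and -0.95. HSP90B1 was uneven, at 13690 and 14930 CPM in NC and at 11970 and 2458 CPM in OE. XBP1, HERPUD1, ERN1 and EDEM1 overlapped between the groups, and the co-chaperone DNAJB9 was the member above both NC libraries, with 0.79 (SE 0.31). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of the 27 members passed over all genes and 0 passed adjusted over the list alone, where the smallest adjusted p was 0.153. The mean of the list stayed between -1 and -0.76 when each library was left out in turn, and the list was called by camera in all 4 of those fits.

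**Figure D2:**
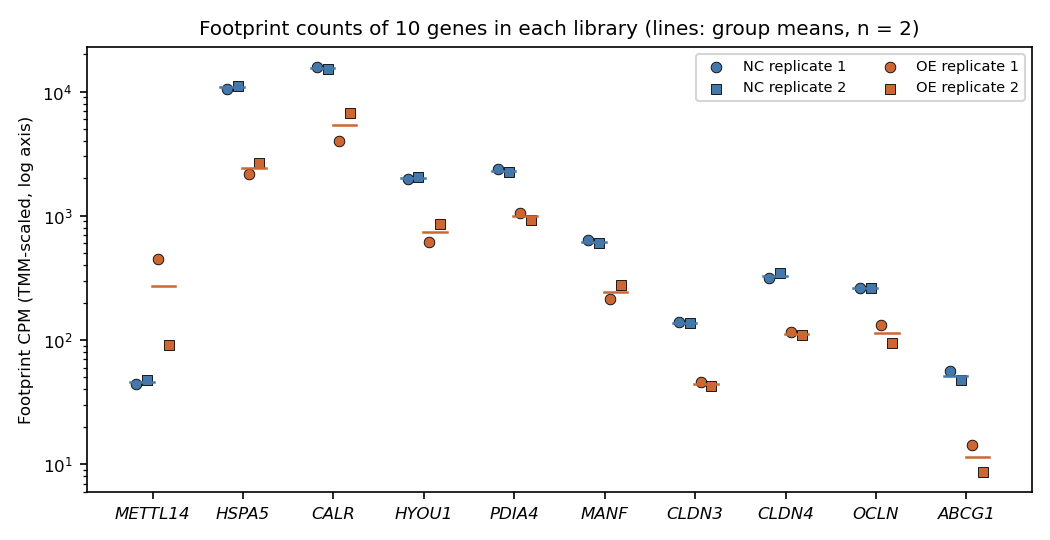
Footprint level of 10 genes (CPM after TMM scaling, log axis) in each of the 4 libraries, with group means over n = 2 as lines and no error bars. HSPA5, CALR, HYOU1 and PDIA4 were picked outside the naming rule, and the uneven HSP90B1 and the higher DNAJB9 are not shown. METTL14 lies higher in OE, at 448 and 91.2 CPM against 44.6 and 47.6 CPM in NC, and the other 9 genes lie lower in both OE libraries, HSPA5 at 2175 and 2638 CPM against 10530 and 11120 CPM; none passed the adjusted threshold of edgeR's quasi-likelihood test.

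Epithelial genes were called lower as a list. Among the members with the smallest p, the claudins CLDN3 and CLDN4, which seal the space between epithelial cells, had log2 fold changes of -1.64 (SE 0.31) and -1.55 (SE 0.37), with CLDN3 at 138 ± 2.24 CPM in NC and 44.3 ± 2.20 CPM in OE (SD, n = 2). Occludin (OCLN) had -1.22 (SE 0.38). Over 30 members the mean log2 change was -0.47 (camera adjusted p = 0.00201; adjusted p = 0.818 with an estimated correlation), with 16 members lower in both OE libraries and 2 higher. Among random expression-matched lists it lay at percentiles 0.39 and 7.35 in OE replicates 1 and 2. The list of goblet and enteroendocrine markers fell as well, with a mean of -0.68 over the 10 of its 26 members that were tested (camera adjusted p = 0.00334; adjusted p = 0.818 with an estimated correlation) and 7 members lower in both OE libraries, at percentiles 0.19 and 1.61 of random expression-matched lists in OE replicates 1 and 2. These 10 were mucins, trefoil peptides and other secretory genes, while the 16 members not tested included every enteroendocrine marker, such as CHGA and NEUROD1. In OE replicate 2 the list had a median of -0.52, near the -0.46 of 79 genes translated at the ER outside the chaperone list. The fall there was therefore not particular to goblet genes. MUC2 and REG4, counted among the 7, had 0.095 and 0.286 CPM in OE replicate 1, at or below the value of 3 counts. Among the members with the smallest p, the mucin MUC5AC had -0.79, the trefoil peptide TFF3 -0.83 and AGR2, a disulfide isomerase of mucin-secreting cells, -1.12. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 members of either list passed over all genes or adjusted over the list alone. Without OE replicate 1 neither list was called, with means of -0.30 (camera adjusted p = 0.116) for the epithelial list and -0.20 (camera adjusted p = 0.247) for the goblet list, while without OE replicate 2 the goblet mean was -1.16.

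Type I interferon response genes, fatty acid synthesis genes and hypoxia genes were also called lower by camera. Their medians lay at percentiles 0.02, 9.03 and 3.67 of random expression-matched lists in OE replicate 1, and at 0.30, 0.38 and 1.17 in OE replicate 2. For the interferon list the mean log2 change was -0.45 over 37 members, of which 17 were lower in both OE libraries and 4 higher (camera adjusted p = 0.00116; adjusted p = 0.818 with an estimated correlation). IFIT1, which binds foreign RNA ends, had 79.5 and 110 CPM in NC and 36.0 and 53.1 CPM in OE; IFI44 had a log2 fold change of -2.05 and OASL -0.82, while the RNA sensor DDX58 had -1.53, or -0.23 when its 2 gene models were summed. The NC libraries also differed on this list, with a median of -0.24 for replicate 1 minus replicate 2. In the fatty acid list, 14 of 19 members were lower in both OE libraries and 0 higher, with a mean of -0.46 (camera adjusted p = 0.00116; adjusted p = 0.818 with an estimated correlation). The elongase ELOVL6 had -0.94 (SE 0.30) and the acyl-CoA synthetases ACSL3, ACSL4 and ACSL5 had -0.75, -0.74 and -0.63. Hypoxia genes had a mean of -0.27, which was 0.03 with library totals as the only scaling (camera adjusted p = 0.0334; adjusted p = 0.818 with an estimated correlation), with 11 of 22 members lower in both OE libraries. The demethylase KDM3A had -1.02 and the mitophagy receptor BNIP3L -0.80, while DDIT4, an inhibitor of mTORC1, had 247 CPM in OE replicate 1 and 39.0 CPM in OE replicate 2. In none of the 3 lists did a member pass by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over all genes (0) or adjusted over the list alone (0). Without OE replicate 1 the camera adjusted p was 0.0698 for the interferon list and 0.0583 for the fatty acid list, whose mean was then -0.29. Without NC replicate 2 it was 0.0527 for the interferon list, and for hypoxia it was 0.169, 0.138 and 0.172 without NC replicate 1, NC replicate 2 and OE replicate 2.

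Lists of energy metabolism and protein turnover had medians below NC in OE replicate 1 and above NC in OE replicate 2. The nuclear encoded respiratory chain had a median of -1.17 in OE replicate 1 and 0.08 in OE replicate 2, the proteasome -1.42 and 0.25, glycolysis -1.43 and 0.12, and mitochondrial ribosomal proteins -1.03 and 0.33. Their means over both OE libraries were -0.56, -0.58, -0.51 and -0.31, with camera adjusted p of 1.61e-07, 0.00112, 0.00790 and 0.00790, and adjusted p = 0.818 with an estimated correlation for each. Members lower in both OE libraries numbered 27 of 76, 4 of 35, 7 of 23 and 5 of 77. ATP5ME, a subunit of ATP synthase, was even across replicates at 286 and 296 CPM in NC and 151 and 132 CPM in OE, whereas the proteasome assembly factor POMP had 339 and 370 CPM in NC and 95.6 and 212 CPM in OE. Of glycolytic genes the glucose transporter SLC2A3 had -0.93 and hexokinase HK2 -0.90, while PFKFB3, which makes an activator of phosphofructokinase, was higher in both OE libraries with 0.78. The means turned to 0.06, 0.24, 0.11 and 0.35 without OE replicate 1, and were -1.18, -1.39, -1.14 and -0.97 without OE replicate 2. Without OE replicate 1 camera called the proteasome (adjusted p = 0.00767) and mitochondrial ribosomal proteins (adjusted p = 2.41e-06) as higher, the reverse of their calls over all libraries, and did not call the respiratory chain (adjusted p = 0.366) or glycolysis (adjusted p = 0.302). Among random expression-matched lists these 4 lay at percentiles of 0.08 or less in OE replicate 1, and at 88.6, 98.9, 76.6 and 100 in OE replicate 2. The spliceosome list had a mean of -0.40 over 44 members, 20 of them lower in both OE libraries, among them SF3B1, a core factor of branch point recognition, with -1.15 (SE 0.34). KRAB zinc finger transcription factors were the list that camera called higher, with a mean of 0.36 over 49 members, of which 15 were higher in both OE libraries and 5 lower. The member with the smallest p, ZNF16, lay lower with -1.08, followed by ZNF77 with 0.80, ZNF81 with 1.12 and ZNF41 with 0.84. The spliceosome and zinc finger lists had camera adjusted p of 0.00114 and 0.00633, with adjusted p = 0.818 with an estimated correlation for both. Neither stood apart from random expression-matched lists, with percentiles of 34.8 and 8.10 for the spliceosome and 86.2 and 52.8 for the zinc fingers in OE replicates 1 and 2. Without OE replicate 1 their means were -0.07 and 0.01 and neither was called, and without OE replicate 2 they were -0.73 and 0.70. In these 6 lists 0 members passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes and 0 adjusted over the list alone.

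**Figure D3:**
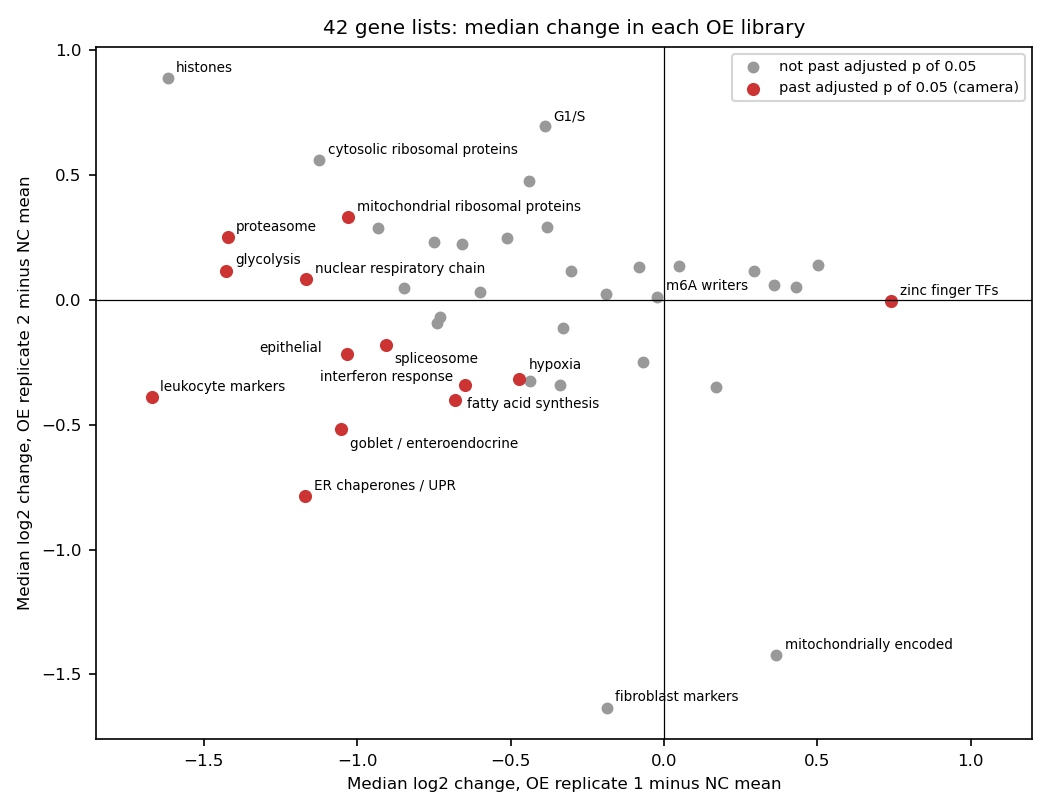
Median log2 change of each of the 42 gene lists in OE replicate 1 (horizontal axis) and OE replicate 2 (vertical axis), each against the NC mean. Red points are the 13 lists past an adjusted p of 0.05 by camera, all of which missed it with an estimated correlation; ER chaperones lie at -1.17 and -0.79, while the proteasome lies at -1.42 and 0.25.

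The lists of cytosolic ribosomal proteins, initiation factors, histones, mitochondrially encoded genes and the ATF4 response were not called by camera. Cytosolic ribosomal proteins had a median of -1.12 in OE replicate 1 and 0.56 in OE replicate 2, and a mean of -0.23 that was 0.07 with library totals as the only scaling (camera adjusted p = 0.102). RPL41 had 432 and 377 CPM in NC and 200 and 138 CPM in OE, while RPS2 had 907 and 724 CPM in NC and 1625 and 1853 CPM in OE. Translation initiation factors had a mean of -0.25, or 0.06 with library totals as the only scaling (camera adjusted p = 0.0775). Among random lists matched on expression, ribosomal proteins lay at percentiles 77.6 and 100 in OE replicates 1 and 2, and initiation factors at 99.2 and 99.2. The medians of the initiation factors were -0.51 and 0.25, so in OE replicate 1 they fell less than the random lists and were not raised. The translation repressor EIF4EBP1 had a log2 fold change of 0.88, with 16.2 and 16 CPM in NC and 34.5 and 24.7 CPM in OE, and PDCD4, an inhibitor of the helicase EIF4A, had -0.64. Replication dependent histones had medians of -1.62 and 0.89 in the OE libraries (camera adjusted p = 0.0685), and genes encoded on the mitochondrial genome had 0.37 and -1.42 (camera adjusted p = 0.0862). The histone list had a mean of -0.43 in log2 CPM and 0.06 in edgeR's fold changes. MT-CO1, a subunit of cytochrome c oxidase, had 3332 and 3831 CPM in NC and 2135 and 773 CPM in OE. The amino acid response list of ATF4 had medians of 0.17 and -0.35 in OE replicates 1 and 2, at percentiles 100 and 0.23 of random lists. Its mean was 0.01 while its camera test pointed down (adjusted p = 0.369). The amino acid transporters SLC7A1 and SLC7A11 had log2 fold changes of -1.18 and -0.84.

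Enzymes of fluoropyrimidine metabolism, which activate, degrade or are inhibited by 5-FU, did not pass as a group, with a mean of 0.09 over 33 members (camera adjusted p = 0.405). This mean was 0.50 without OE replicate 1 and -0.31 without OE replicate 2. Within the group, uridine-cytidine kinase UCK1 had 9.68 and 8.85 CPM in NC and 21.5 and 21.8 CPM in OE, a log2 fold change of 1.23 (SE 0.30). Uridine phosphorylase UPP1 had 0.88, and CAD, which starts de novo pyrimidine synthesis, had -0.80 at 163 and 174 CPM in NC and 95.5 and 98.0 CPM in OE. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 members passed over all genes or adjusted over the list alone, where the smallest adjusted p was 0.317. Thymidylate synthase (TYMS), the target of 5-FU and also picked after its values were seen, had 184 and 166 CPM in NC and 106 and 436 CPM in OE.

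Across all 12560 genes tested, 0 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.734. At an unadjusted p below 0.05 there were 691 genes, 374 higher and 317 lower in OE, where chance alone gives 628. The DESeq2 Wald test called 25 genes (12 higher, 13 lower) and edgeR's likelihood ratio test 29 (11 higher, 18 lower), with 15 in common. Of these 15, 12 had fractional counts, 10 were readthrough models or shared their symbol with another model, and 5 had 0 counts in both libraries of a group. The 3 with whole counts only were HSPA5, ABCG1 and MALL. Both OE libraries lay above both NC libraries for 2496 genes (19.9%) and below them for 2566 genes (20.4%). Chance gives 16.7% each way only where all 4 libraries vary alike. The OE libraries varied more than the NC libraries, with an SD of the log2 difference between replicates of 1.30 against 0.46. That raises the share reached without a shared change, so these shares do not show an excess. Leaving out OE replicate 1 raised the count of the quasi-likelihood test to 4226 genes, leaving out OE replicate 2 to 7675, and leaving out NC replicate 1 or NC replicate 2 to 9 or 3. In counts simulated with the spread of the 4 libraries over 12352 genes, the test recovered 23% of 4-fold changes and 96% of 16-fold changes. The simulation gave both groups the same spread, unlike the data, so these shares do not show which changes could be found here. The H2AC7 model ENSG00000282988, with a log2 fold change of -6.76, had an adjusted p of 0.734 by the quasi-likelihood test.

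None of the genes named for their small p passed that test. Of those lower in OE, the sterol transporter ABCG1 had 51.7 ± 6.32 CPM in NC and 11.4 ± 3.92 CPM in OE (SD, n = 2), a log2 fold change of -2.19 (SE 0.38). Nestin (NES), an intermediate filament protein, had 46.2 ± 5.23 and 14.5 ± 0.0323 CPM, and the guidance factor SEMA3A 74.2 ± 5.93 and 25.3 ± 2.39 CPM. The glucose transporter SLC2A4 had -1.77, the GABA receptor subunit GABRD -2.02, LYPD3 -1.66 and the secreted neuropeptide precursor VGF -1.48. Of those higher in OE, RDH13, a mitochondrial retinol dehydrogenase, had 10.1 ± 1.83 CPM in NC and 38.7 ± 12.7 CPM in OE, a log2 fold change of 1.94 (SE 0.38). The helicase DHX34, which acts in nonsense-mediated decay, had 1.29 (SE 0.29), and RAD9A, part of the DNA damage checkpoint clamp, 1.40 (SE 0.34). FBRSL1 had 1.40, FAM13B 1.92, AJUBA 1.80, NAA40 1.58, HOMEZ 1.27, ATAD3B 1.61 and CBWD5 1.83, the last pair having close paralogs with which reads can be shared. Several of the smallest p-values came from gene models that share their symbol with another model, and whether the models overlap or divide reads was not tested. H2AC7 (ENSG00000282988) had a log2 fold change of -6.76, which was -0.64 when both models were summed. SMIM7 had 3.28 for ENSG00000268790 and -2.14 for ENSG00000214046, and -0.59 summed. CLN3 (ENSG00000261832) had -1.95, and -0.64 summed, while FDX2 kept 1.42 after summing against 1.44 before. FMC1-LUC7L2, a readthrough model over 2 adjoining genes, had -3.04.

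Leukocyte markers, fixed as a check for another cell type, were called lower by camera, at percentiles 0.03 and 20.2 of random expression-matched lists in OE replicates 1 and 2, with a mean of -1.18 over 5 members (camera adjusted p = 0.00334; adjusted p = 0.818 with an estimated correlation). CD14, the co-receptor for lipopolysaccharide, had 11.5 and 8.97 CPM in NC and 2.48 and 2.80 CPM in OE, and CD68, a lysosomal membrane protein, had 70.6 and 75.5 CPM in NC and 40.8 and 28.7 CPM in OE. CD14 was the 1 member that passed edgeR's quasi-likelihood test adjusted over the list alone (Benjamini-Hochberg adjusted p = 0.0279), and 0 passed over all genes. The other 15 markers, among them PTPRC and CD3E, had at most 5 counts in any library and were not tested. The list was not called without OE replicate 1, where the mean was -0.80 (camera adjusted p = 0.0903).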

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

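The added alternatives (counts summed per symbol, thinned libraries, quality weights) were chosen after seeing the data, and the cause of the changes below was not tested. The count of genes past the threshold was 0 with the quasi-likelihood test. It stayed 0 with RLE or total-count scaling, either filter, removal of abundant genes, summed symbols, thinning and quality weights. It was 25 with the DESeq2 Wald test, where METTL14 had 2.51, 29 with the likelihood ratio test and 24 with the replicate block, neither of which called METTL14 (adjusted p = 0.266 and 0.620, edgeR). Leaving out libraries gave 3 to 7675 genes, and 0.99 to 3.28 for METTL14; these fits leave a lone library in a group and assume that it varies as the other group does. The labels do not say whether a replicate number marks a shared experiment of NC and OE. The replicate differences of NC and OE correlated at -0.097 across genes. This does not settle it, since the OE libraries differed from each other far more than the NC libraries. Of the 24 genes called with the block, 15 were among those of DESeq2. Called lists numbered 13, and 12 to 18 under other scalings, filters, weights, thinning and the block, but 0 with an estimated correlation and 0 by fry, and 13 to 22 when libraries were left out. Limma on log2(CPM + 1) gave 13; lists have no separate value under the likelihood ratio test or DESeq2. FPKM and TPM settings were not run, as the files hold counts.

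With library totals as the only scaling the median of edgeR's log2 fold change over all genes was 0.40 against 0.09 with TMM, and signs turned for CBLL1 (0.051), VIRMA (0.29), METTL3 (0.18), RBM15 (0.32), MT-ATP6 (0.074), MT-CYB (0.10), hypoxia (0.032), m6A erasers and readers (0.12), cytosolic ribosomal proteins (0.074) and initiation factors (0.055). Signs also turned without the filter for m6A writers (-0.015) and the ATF4 list (-0.008), with 50 counts for RBM15 (0.001), with thinning for RBM15 (0.04) and with quality weights for H2BC13 (-0.008).

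Signs turned with 1 library left out for the following log2 changes. Among genes, the ranges were -0.077 to 2.59 for DDIT4, -2.198 to 0.104 for ZC3H13, -0.36 to 0.67 for METTL16, -0.02 to 0.33 for WTAP, -1.07 to 0.39 for VIRMA, -0.42 to 0.16 for METTL3, -0.093 to 0.203 for METTL5, -0.18 to 0.09 for RBM15, -0.44 to 2.21 for EIF4EBP2, -2.56 to 0.026 for MT-CO2, -1.49 to 0.21 for MT-ATP6, -1.78 to 0.30 for MT-CYB, -0.69 to 1.72 for H2BC17 and -1.16 to 1.83 for H2BC13. Among lists they were -0.97 to 0.35 for mitochondrial ribosomal proteins, -1.18 to 0.061 for the nuclear respiratory chain, -1.14 to 0.11 for glycolysis, -1.39 to 0.24 for the proteasome, -0.96 to 0.51 for cytosolic ribosomal proteins, -1.59 to 0.74 for histones, -1.29 to 0.23 for the mitochondrially encoded chain, -0.31 to 0.50 for fluoropyrimidine metabolism, -0.18 to 0.21 for m6A writers and -0.31 to 0.33 for the ATF4 list. Depth limits OE replicate 1 most: 3 counts there equal 0.286 CPM, and the total was 7742274.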

Other observations

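Ferritin messages differed sharply between the OE libraries. FTL and FTH1, the light and heavy chains of the iron store, had 483 and 557 CPM and 1100 and 1299 CPM in NC. In OE replicate 1 they had 2997 and 5749 CPM, and in OE replicate 2 they had 230 and 535 CPM. TTN, the gene of the giant muscle protein titin, had 657 CPM in OE replicate 1 and 29.8 CPM in OE replicate 2, against 121 and 154 CPM in NC. The cytoskeletal linkers SPTBN1 and MACF1 had 1021 and 322 CPM in OE replicate 1, and 97.48 and 41.4 CPM in OE replicate 2. Histone H3C12 went the other way, at 221 and 1851 CPM. These genes were picked after their values were seen, from among genes with a wide gap between the OE libraries.

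The lists not described so far missed the threshold of camera after Benjamini-Hochberg adjustment, and their mean log2 changes hold for TMM scaling only. DNA repair had 0.24 (adjusted p = 0.0580), G1/S genes 0.21 (0.0775), immediate early genes 0.20 (0.116), AKT and mTOR signalling 0.20 (0.231), p53 targets 0.16 (0.312), apoptosis regulators 0.11 (0.457) and ubiquitin genes 0.06 (0.657). Elongation and termination factors had -0.34 (0.0756), enterocyte markers -0.31 (0.0930), ABC drug transporters -0.28 (0.0775), mesenchymal genes -0.25 (0.0775), G2/M genes -0.18 (0.102) and autophagy genes -0.17 (0.126). MYC and ribosome biogenesis genes had -0.16 (0.102), colorectal stem cell markers -0.16 (0.461), cholesterol synthesis -0.12 (0.425), ferroptosis genes -0.12 (0.312) and cytosolic heat shock proteins -0.10 (0.492). Fibroblast markers had -0.66 over 5 tested members (0.0643). Wnt genes had a mean of -0.05 and a median of 0.01 (0.445), and NF-kB targets a mean of 0.03 and a median of -0.01 (0.975). Against random expression-matched lists, 3 lists lay below the 2.5th percentile in both OE libraries, namely ER chaperones, interferon genes and goblet markers. The other lists that camera called lower did not, and the proteasome and mitochondrial ribosomal proteins lay below it in OE replicate 1 and near the top of the random lists in OE replicate 2. Initiation factors lay near the top in both, at percentiles 99.2 and 99.2. In OE replicate 1 they still lay below NC, with a median of -0.51 against -0.84 for the random lists.

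In the 3 paragraphs that follow and the last, the tests of coding length in OE replicate 1, of other ER messages and of other junction genes were written before their results were seen, on lists made after the main results; the remaining tests were chosen after. OE replicate 1 stood apart from the other 3 libraries. Depth is argued against as the cause: with every library thinned to the smallest total, the 3 deeper libraries still correlated at 0.946 or more, and OE replicate 1 with them at 0.874 at most. A graded effect of METTL14, the highest in OE replicate 1, is also argued against as the source of most change over all genes. The changes of the OE libraries against separate NC libraries correlated at 0.057 and -0.011 across genes. This does not address a graded effect on a smaller set of messages, which shifts of each library in opposite ways could hide. Still open are a broad background of reads that evens out levels, since the change of OE replicate 1 fell with the NC level (Spearman's rho -0.534 across genes, against 0.008 for OE replicate 2), and coding length, since a hand-made list of 83 genes known for long coding sequences, with no lengths measured, lay at percentile 100 of random lists in OE replicate 1 (median 0.61) and at percentile 0 in OE replicate 2 (median -0.92). These may reflect how each library was digested or recovered, which was not tested. An effect of METTL14 that is not graded, or on a smaller set of messages, also stays open.

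ER chaperones were lower in both OE libraries, with a median of -0.79 in OE replicate 2, at percentile 0 of random expression-matched lists. Lower recovery of all messages translated at the ER in both OE libraries is argued against, since 79 other such genes lay at percentile 0 in OE replicate 2 but at 58.6 in OE replicate 1. In OE replicate 2 these had a median of -0.46, with the chaperones lower by -0.325 (two-sided permutation p = 0.0054 across genes), and in OE replicate 1 the chaperones were lower by -0.187 (p = 0.189), so a fall of ER messages in OE replicate 2 stays open as part of the pattern. With library totals alone the list mean was -0.579 in log2 CPM, where the median of all genes in log2 CPM was 0.311. The list thus lay below NC on that scale too. Scaling moves all genes of a library alike, so the gap to other genes could hardly change and does not test scaling. Coding length, as far as the hand-made list stands for it, is argued against by the chaperones' percentiles of 0.88 and 0 in the OE libraries. The hand-made list went opposite ways in these libraries. The evened-out levels of OE replicate 1 stay open as part of the fall in that library. There the tenth of genes with the highest NC level had a median of -1.08, against -1.17 for the chaperones. The matching of the random lists did not fully remove a dependence on NC level. An effect of METTL14 on these messages stays open and was not tested, as do a state of the cultures unrelated to METTL14 and, without libraries of total RNA, message amount and ribosome occupancy as its basis.

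Gene models with fractional counts or a shared symbol were over-represented among the 100 smallest p-values. Fractional counts marked 42 of these against 27.6% of all tested genes (odds ratio 1.91, two-sided Fisher's exact p = 0.00222), and 20 were readthrough models or shared a symbol against 4.98% (odds ratio 4.9, p = 8.11e-08). This is consistent with reads being divided differently between models in the libraries, as a hypothesis, for part of the list. The other 58 had whole counts only, which does not exclude reads shared between models.

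A hypothesis that cell junction genes in general were lower, beyond the claudins and occludin, was not borne out in both OE libraries. A list of 32 junction genes outside the epithelial list lay at percentile 0 of random lists in OE replicate 2 (median -0.48) but at 17.9 in OE replicate 1 (median -0.51).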
